A study of Homo sapiens with 6 samples.

How the data were processed

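RNA was measured in VCaP cells, a human prostate cancer cell line that carries the TMPRSS2-ERG gene fusion. Per the labels, the cells carried either a short hairpin RNA (shRNA) against NEDD9 (shNEDD9) or a non-targeting control shRNA (shNTC), and both were kept in medium with 10% foetal bovine serum. Each group held 3 libraries, and the design text calls them biological triplicates. Samples were grouped by the shRNA named in their titles. Total RNA was isolated on columns and made into libraries with a stranded total RNA kit, per the labels' protocols.

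The deposited table holds whole-number counts of reads per gene, which were not normalised. The submitters' processing notes name FastQC 0.11.5, cutadapt 1.9, STAR 2.5.3a, featureCounts and Subread 1.6.2 as tools, and hg19 and GRCh38 as builds, without saying what each build was used for. The annotation release and the strand setting of the counting were not given in the sources used here. Without the strand setting, reads of a gene and of its antisense partner may have been mixed, and reads shared by near-identical genes or by genes with common exons may have been dropped or split. All 58735 gene identifiers of the table occur in GENCODE release 29 (GRCh38), from which coordinates and gene types were taken. 1 row without an identifier was left out, and 27 symbols that a spreadsheet had turned into dates were restored from their identifiers. The 460 identifiers without a symbol held 0.00915% of the counts.

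Total counts per library were 7492244, 3217276 and 6452350 in shNTC and 5956486, 7806980 and 9902002 in shNEDD9. A count of 3, taken as the floor of detection, equals 0.303 to 0.932 CPM (counts scaled to the library total) across the libraries. Floors cover counting error only, and the binomial intervals given below cover only the sampling of genes.

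Differences between shNEDD9 and shNTC were tested with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3 on the deposited counts, with TMM scaling factors (0.99 to 1.01) and no covariate. Genes with low counts were removed with filterByExpr at its default minimum count of 10, which left 13958 genes. p-values were adjusted by the Benjamini-Hochberg method over these genes, and an adjusted p under 0.05 was called a change. Fold changes are shNEDD9 over shNTC, and errors of log2 fold changes are approximate standard errors (SE). Each is the absolute log2 fold change before edgeR's moderation, divided by the square root of the test's F statistic. Where a group had 0 counts this error is not usable. CPM values were computed with the TMM factors and are given as mean ± SD with n = 3 libraries per group. Adjusted p-values below 1e-300 are given as such.

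28 gene lists that fit prostate cancer cells, NEDD9 and possible other cell types were fixed before the data were examined, as were the comparison, the test and the rule for named genes. Lists with at least 5 genes left after the filter were tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01, adjusted over the 27 lists tested. Camera with a correlation estimated for each list, and fry, a rotation test of whether the genes of a list move on balance one way, were run beside it.

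The rule for named genes took NEDD9, BCAR1, EFS, CASS4, AURKA, PTK2, SRC, ERG, TMPRSS2 and KLK3, among others, by prior choice. It added the 12 largest increases and the 12 largest decreases among changed genes with a mean of at least 5 CPM whose groups did not overlap. From each list it took up to 4 changed members with the largest log2 fold changes at a mean of at least 1 CPM, or the 2 most abundant members where none changed. The 5 genes of smallest p in each direction completed it. Some genes that the rule took are not reported here.

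Replicates were compared by a chi-square test of their counts over genes with at least 20 counts in a pair. The procedure was tested on counts simulated for 13741 genes from the means and library sizes of this comparison. It recovered 58% of genes changed by 1.25-fold, 84% at 1.5-fold, 96% at 2-fold and 98% at 4-fold, and 13 of its 181 calls (7.18%) were false. The changed genes, 50 for each fold, were drawn only from genes above a minimum of counts, and every gene had the common dispersion. Recovery of genes with few counts, or when most genes change, was not measured. In a simulation of the list test, the 1 changed list was called and none of the other 26 was (0 calls). Its genes were drawn independently of each other, so it could not test the preset correlation. The called lists of the real data had estimated correlations of 0.05 to 0.83.

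The alternatives were RLE and upper-quartile factors, library totals alone, no count filter, a minimum mean of 1 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, small RNA and mitochondrial genes left out, and each library left out in turn. Thinning of every library to the smallest total, an assumed biological coefficient of variation of 10%, removal of genes in shifted chromosome runs, removal of NEDD9 from the focal adhesion list and a loess correction for transcript length and GC content were added after the results were seen. Figures were drawn with matplotlib 3.10.9.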

Results

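The study asked which genes change their expression when NEDD9 is silenced in VCaP prostate cancer cells. Gene counts were compared between 3 shNEDD9 and 3 shNTC libraries of 3217276 to 9902002 counts each. NEDD9 encodes a Cas family scaffold protein of focal adhesions that also binds the mitotic kinase AURKA.

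NEDD9 (ENSG00000111859, GRCh38 chromosome 6, 11183298 to 11382348, minus strand) was lower in every shNEDD9 library, at 137 ± 1.03 CPM against 355.7 ± 14.3 CPM in shNTC (SD, n = 3 each). This is a 2.62-fold decrease, or 61.8% (log2 fold change -1.39, SE 0.04, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p below 1e-300). AURKA (ENSG00000087586, chromosome 20, 56369389 to 56392337) rose by 1.58 on the log2 scale, from 36.3 ± 2.03 to 109.6 ± 4.15 CPM (n = 3 each), while the Cas family member BCAR1 fell by 0.53 on the log2 scale (SE 0.06). PTK2, which encodes focal adhesion kinase, fell by 0.44 (SE 0.04). SRC, a kinase that phosphorylates Cas proteins, stood at 358.4 ± 9.71 against 376.9 ± 18.6 CPM (n = 3 each) and was not called (log2 fold change -0.06, edgeR adjusted p = 0.0674). It passed without shNTC replicate 3 (edgeR adjusted p = 0.0193), without shNEDD9 replicate 3 (edgeR adjusted p = 0.0386) and without genes in shifted chromosome runs (edgeR adjusted p = 0.0416), and its adjusted p ranged from 0.0193 to 0.637 over 18 alternatives. EFS and CASS4, the remaining members of the Cas family, had 1 and 3 counts over all 6 libraries and were not tested.

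Androgen-regulated genes went in both directions. KLK3 (ENSG00000142515, chromosome 19, 50854915 to 50860764), which encodes prostate-specific antigen, rose 3.36-fold, from 267.4 ± 8.40 to 904.4 ± 19.1 CPM (n = 3 each). TMPRSS2, the androgen-regulated partner of the fusion gene, fell by 0.63 on the log2 scale (SE 0.04), and ERG, its transcription factor partner, fell by 0.44 (SE 0.04). Each of these 3 changes was past the threshold (edgeR with Benjamini-Hochberg adjustment, adjusted p of 3.84e-34 for ERG, the weakest).

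**Figure D1:**
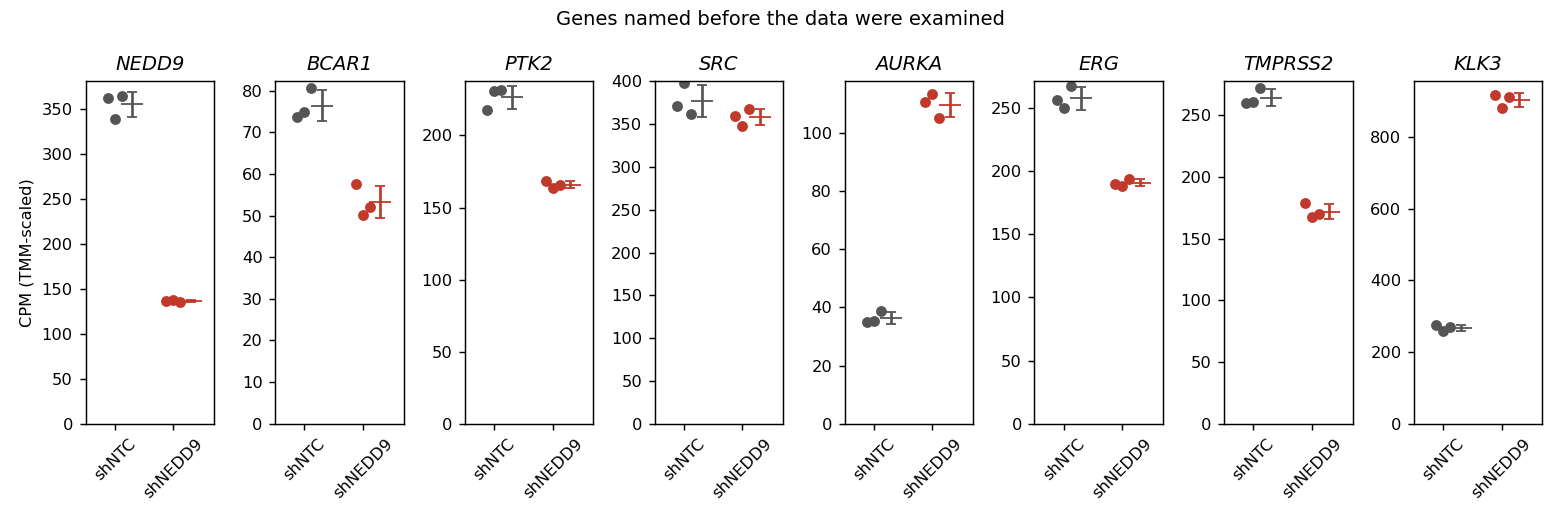
CPM (counts scaled to library size with TMM factors, linear axes from 0) of 8 genes chosen before the data were examined, with 1 point per library and the mean ± SD of 3 libraries to the right of the points. NEDD9 sits at 137 CPM in shNEDD9 and 355.7 CPM in shNTC, and SRC is the 1 gene of the 8 that was not called.

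Of 13958 genes tested, 4950 were higher and 5014 lower in shNEDD9 at an adjusted p under 0.05, which is 71.4% of them. 1070 genes were at least 2-fold higher and 1287 at least 2-fold lower. The groups did not overlap in 10020 of the tested genes, where chance gives 10%. The median log2 fold change of all tested genes was 0.00. The spread between replicates was small, with a common biological coefficient of variation of 1.65%, and p-values measure only the spread between these libraries, which may be technical. Counts of replicate pairs differed by slightly more than sampling noise (chi-square over degrees of freedom 1.14 to 1.21). This argues against 1 library counted more than once, but cannot tell separate cultures from separate preparations of 1 culture. Each library was counted as 1 replicate.

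The largest increases included several well-measured protein-coding genes. CHAC1, a glutathione-degrading enzyme gene (ENSG00000128965, chromosome 15, 40952962 to 40956519), rose 22.5-fold, from 4.15 ± 0.57 to 92.3 ± 3.99 CPM (n = 3 each). STC2, which encodes the secreted glycoprotein stanniocalcin 2 (ENSG00000113739, chromosome 5, 173314713 to 173329503), rose 18.4-fold to 811 ± 19.0 CPM. The mitochondrial folate enzyme gene ALDH1L2 rose 25.9-fold from 8 counts over the shNTC libraries (41.4-fold without shNTC replicate 2, 16.2-fold with all libraries thinned to the smallest total), and SESN2, a stress-induced inhibitor of mTORC1 signalling, rose 11.7-fold. AJUBA, a LIM-domain scaffold gene, rose 18.7-fold, ULBP1, a ligand of the NKG2D receptor, 11.2-fold, ADM2, a peptide hormone gene, 10.0-fold, and the glycine transporter gene SLC6A9 9.5-fold. TUNAR rose 10.5-fold. The largest increase, that of CCDC144NL-AS1 (103.2-fold, and 66.1-fold without shNTC replicate 3), rested on 4 counts that all lay in shNTC replicate 1. Without that library shNTC had 0 counts, and CCDC144NL-AS1 was at least 84.6-fold higher at a floor of 3 counts over the group. As an antisense transcript it may hold reads of the opposite strand. The increases of the pseudogenes SRP72P2 and SIGLEC16 (23.8-fold and 16.1-fold) are uncertain because near-identical genes may share their reads, and that of SRP72P2 was 15.7-fold after thinning. By smallest p, STC2 was joined by SCD, a fatty acid desaturase gene (5.95-fold), the linker histone gene H1F0 (5.19-fold), PSAT1, an enzyme gene of serine synthesis (6.02-fold), and GARS, the glycyl-tRNA synthetase gene (4.41-fold).

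The largest decrease was that of TRPA1, an ion channel gene, which fell by 6.58 on the log2 scale (SE 0.28) to 5 counts over the shNEDD9 libraries (log2 fold change -7.24 without shNEDD9 replicate 2). SULT1C4, a sulfotransferase gene, fell by 5.72, and CRISPLD1 fell by 5.59, from 219.3 ± 6.28 to 4.57 ± 0.57 CPM (n = 3 each). COL17A1, a hemidesmosome collagen gene, fell by 5.02, VSTM2A by 4.91, VTN, which encodes vitronectin, by 4.49, BEX1 by 4.39, CEACAM7 by 4.32, and LGALS3, which encodes galectin 3, by 4.26. The log2 fold change of BEX1 was -5.05 without shNEDD9 replicate 3, and those of VSTM2A and CEACAM7 were -5.99 and -5.27 after thinning. UGT1A1 fell by 4.94, although it shares exons with the other UGT1A genes, and the pseudogene NBPF7 fell by 5.12, and both values are uncertain for shared reads. Among the smallest p-values were also REG4 (8820 ± 241.2 to 565.4 ± 9.92 CPM, 15.6-fold lower), PLA2G2A, a secreted phospholipase gene (14.8-fold lower), IGFBP3, which binds insulin-like growth factors (7.51-fold lower), and WDR7 (9.46-fold lower).

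**Figure D2:**
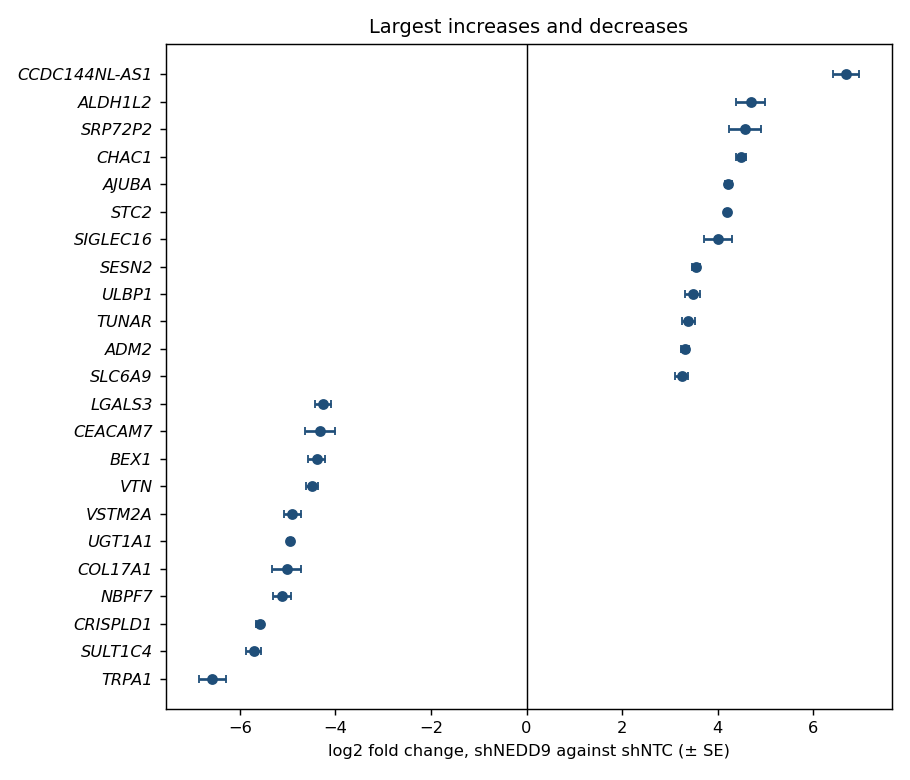
Log2 fold changes (shNEDD9 against shNTC, points) with approximate standard errors (bars) of the 12 largest increases and of 11 of the 12 largest decreases among changed genes with a mean of at least 5 CPM. Values run from -6.58 for TRPA1 to 6.69 for CCDC144NL-AS1.

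Genes of cell division were higher throughout. All 28 genes of the G2/M and mitosis list rose, 26 of them at least 2-fold, with a median log2 fold change of 1.63 (camera with Benjamini-Hochberg adjustment, adjusted p = 8.42e-17, and adjusted p = 0.316 with an estimated correlation). HMMR, a spindle protein gene, rose 6.35-fold (75.2 ± 2.59 against 11.9 ± 0.83 CPM, n = 3 each), the mitotic cyclin gene CCNB2 4.39-fold, the phosphatase gene CDC25C 4.14-fold and CDC20, an activator of the anaphase-promoting complex, 4.01-fold. All 30 genes of DNA replication and E2F targets rose, 22 at least 2-fold, with a median of 1.31 (camera adjusted p = 7.45e-15, and adjusted p = 0.316 with an estimated correlation). Examples were E2F2 (3.75-fold), the thymidine kinase gene TK1 (3.70-fold), the replication licensing gene CDT1 (3.4-fold) and RFC4 (3.07-fold). Adjusted over the list alone, the counts were 28 and 30 as well.

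Lists of biosynthesis and metabolism were also higher. Of 26 genes of the ER stress and amino acid response, 20 rose and 4 fell (median 0.83, camera adjusted p = 1.05e-06, and adjusted p = 0.316 with an estimated correlation), among them ATF3, a stress-induced transcription factor gene (9.31-fold), and MTHFD2, a mitochondrial folate enzyme gene (6.65-fold). Of 29 genes of cholesterol and fatty acid synthesis, 26 rose and 3 fell (median 0.79, camera adjusted p = 3.23e-08, and adjusted p = 0.316 with an estimated correlation). FADS2, a desaturase gene, rose 5.84-fold, whereas SC5D, a sterol desaturase gene, fell by 1.81 on the log2 scale. Of 29 MYC targets and ribosome biogenesis genes, 27 rose and 2 fell (median 0.58, camera adjusted p = 1.12e-08, and adjusted p = 0.316 with an estimated correlation), with TFRC, the transferrin receptor gene, up 2.49-fold, FBL 2.33-fold, DKC1 2.23-fold and MYC 2.09-fold. Of 25 hypoxia and glycolysis genes, 16 rose and 4 fell (median 0.90, camera adjusted p = 0.000566, and adjusted p = 0.316 with an estimated correlation), and adjusted over the list alone 17 rose. VEGFA, an angiogenic growth factor gene, rose 4.50-fold and the lactate dehydrogenase gene LDHA 3.79-fold, while EGLN3, a hydroxylase gene that hypoxia induces, fell by 2.07 and ADM by 1.99. In the other lists of this paragraph the counts adjusted over the list alone equalled those over all genes.

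Of 26 nuclear genes of oxidative phosphorylation, 23 rose and 0 fell, with a median log2 fold change of 0.52 (camera adjusted p = 3.66e-08, and adjusted p = 0.316 with an estimated correlation; the counts were the same adjusted over the list alone). CYC1, a cytochrome gene of complex III, rose 1.84-fold, NDUFV1 1.76-fold, UQCRC2 1.76-fold and COX5B 1.74-fold. Mitochondrially encoded transcripts took a smaller share of the counts, 2.40 ± 0.02% in shNEDD9 against 3.34 ± 0.06% in shNTC (SD, n = 3 each, two-sided exact permutation p = 0.1, the smallest this design allows). Their 13 tested protein-coding genes, looked at after the data were seen, all fell (median -0.42).

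Lists of adhesion, signalling and epithelial genes were lower. Of 28 tested genes of the list of Cas scaffold partners and focal adhesion, 18 fell and 5 rose (median -0.33, or -0.18 after a correction for transcript length and GC content, camera adjusted p = 0.000842, and adjusted p = 0.316 with an estimated correlation). Over the camera alternatives its camera adjusted p ranged from 1.45e-05 to 0.316. The list includes NEDD9, the silenced gene. Without it 17 of 27 fell and 5 rose, over all genes and adjusted over the list alone (median -0.27, or -0.14 after that correction, camera adjusted p = 0.00224, and adjusted p = 0.316 with an estimated correlation). Its largest decreases were the integrin subunit genes ITGB4 (5.91-fold lower, 8.33 ± 0.59 against 49.6 ± 3.58 CPM, n = 3 each) and ITGB6 (4.92-fold lower) and LPXN, which encodes leupaxin (4.89-fold lower). The list of NF-kB and cytokine genes had 14 lower and 1 higher of 16 (median -1.01, camera adjusted p = 0.000446, and adjusted p = 0.316 with an estimated correlation), with the chemokine genes CXCL1 11.8-fold, CXCL3 9.82-fold, CXCL8 7.62-fold and CCL20 5.35-fold lower. Without shNEDD9 replicate 2, CXCL1 was 19.4-fold lower. CXCL1, CXCL3 and CXCL8 lie in a shifted run on chromosome 4, described below, so their decreases may not be independent of each other. Of 20 TGF-beta and BMP genes, 17 fell and 1 rose (median -0.73, camera adjusted p = 5.41e-06, and adjusted p = 0.316 with an estimated correlation). The receptor gene TGFBR2 was 7.36-fold lower, BAMBI 4.24-fold and ID1, a BMP target, 3.47-fold (121.1 ± 0.88 against 422 ± 12.4 CPM). Of 17 MAPK/ERK feedback genes, 13 fell and 3 rose (median -1.41, camera adjusted p = 0.0052, and adjusted p = 0.316 with an estimated correlation), with EGR1 8.33-fold, PHLDA1 7.08-fold, FOS 4.93-fold and SPRY4 3.63-fold lower; after thinning PHLDA1 was 11.9-fold lower.

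Of 27 epithelial and luminal markers, 17 fell and 6 rose (median -0.36, or -0.23 after the correction for length and GC content, camera adjusted p = 0.0116, and adjusted p = 0.316 with an estimated correlation), and the luminal keratin gene KRT8 was 2.70-fold and ELF3 2.37-fold lower. Of 31 androgen-induced genes, 17 fell and 9 rose (median -0.31, or -0.19 after that correction, camera adjusted p = 0.0328, and adjusted p = 0.316 with an estimated correlation). This list holds KLK3, which rose, and SLC45A3 (3.91-fold lower, 174.5 ± 0.35 against 685 ± 20.8 CPM), EAF2 (3.29-fold lower) and KLK4 (3.10-fold lower). Its call ended when genes in shifted chromosome runs were left out (camera adjusted p = 0.0507, range over the camera alternatives 2.26e-05 to 0.316). This removed 1 of its 31 members, HPGD (log2 fold change -1.48), and the median was -0.32 (SD 0.85) against -0.31 (SD 0.86) with it. In all 6 lists that were lower, the counts adjusted over the list alone equalled those over all genes.

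**Figure D3:**
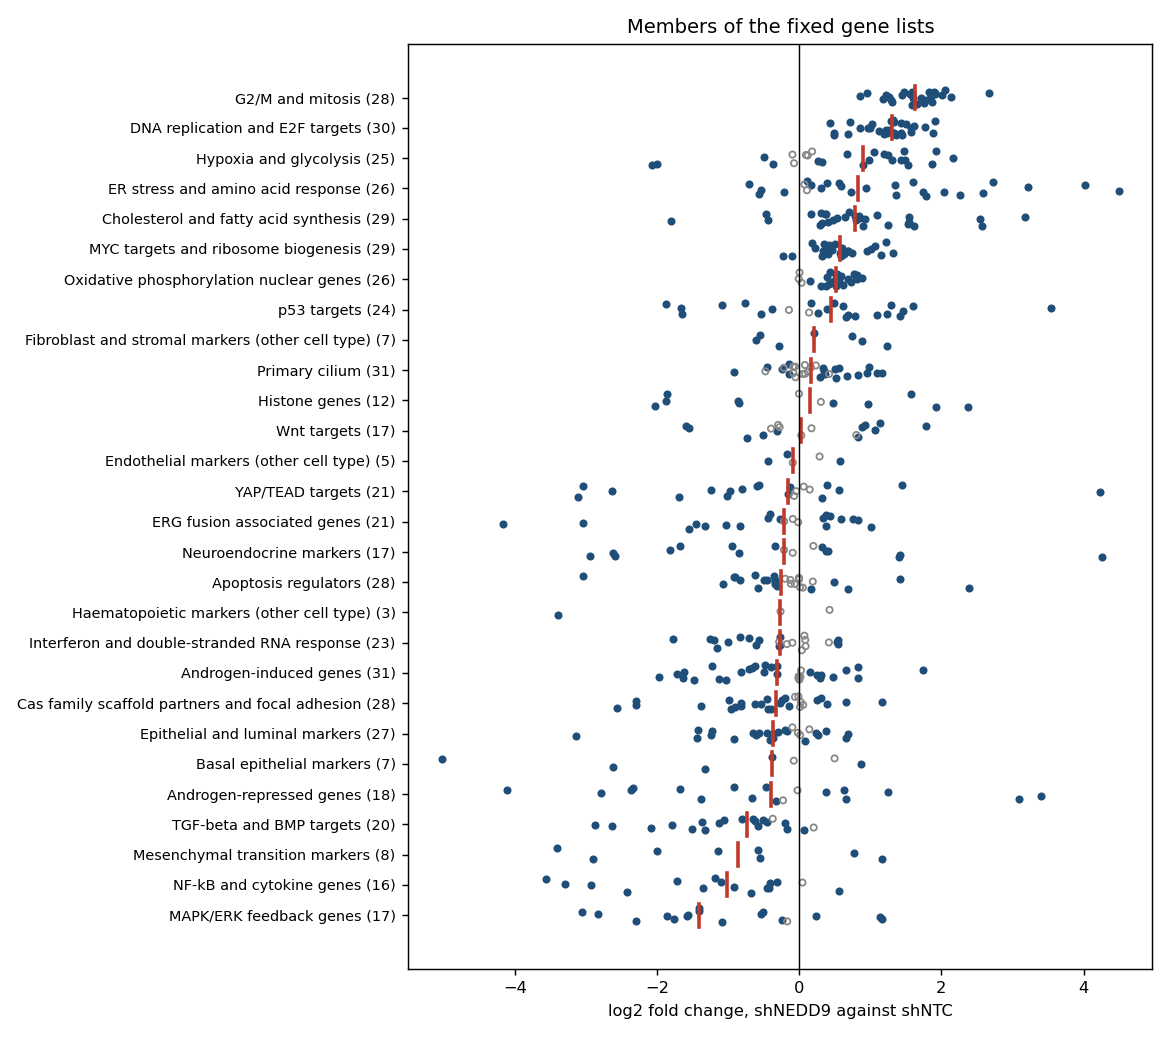
Log2 fold changes (shNEDD9 against shNTC, horizontal axis) of the tested members of each of the 28 fixed lists, with filled points for changed genes, open points for the others and a red line at each median. The number of tested members follows each list's name, and the medians run from -1.41 for MAPK/ERK feedback genes to 1.63 for G2/M and mitosis.

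The other lists were not called by camera, although many members changed. Of 18 androgen-repressed genes, 6 rose and 10 fell (camera adjusted p = 0.0912), with UGT2B15, a steroid-conjugating enzyme gene, 8.56-fold higher and LRRN1 17.3-fold lower; this list was called without shNTC replicate 2 (camera adjusted p = 0.0473), after thinning (0.0304) and without a count filter (0.0132, range over the camera alternatives 0.0132 to 0.344). Of 8 mesenchymal transition markers, 2 rose and 6 fell (camera adjusted p = 0.0551), with N-cadherin (CDH2) 10.6-fold, FN1 7.45-fold and THBS1 4.01-fold lower and LOX 2.23-fold higher (3.85-fold without shNTC replicate 1). That list was called without shNTC replicate 1 (camera adjusted p = 0.0252), shNTC replicate 2 (0.0179), shNEDD9 replicate 2 (0.0405) or shNEDD9 replicate 3 (0.0336). It was also called with limma-voom (camera adjusted p = 0.0143), without a count filter (0.0401) and after thinning (2.18e-05), and its camera adjusted p ranged from 2.18e-05 to 0.344 over the camera alternatives. Of 21 ERG-associated genes, 8 rose and 10 fell (camera adjusted p = 0.382), among them ADAMTS1, a protease gene, 8.19-fold lower. Of 7 basal markers, 1 rose and 4 fell (camera adjusted p = 0.159), with COL17A1, named above, lower. This list was called after thinning (camera adjusted p = 0.0269) and without a count filter (0.0266, range over the camera alternatives 0.0266 to 0.404). Of 17 neuroendocrine markers, 6 rose and 8 fell (camera adjusted p = 0.382), with SCG5 19.2-fold higher from 6 counts over the shNTC libraries and UCHL1 6.11-fold lower. Without shNTC replicate 1 SCG5 was 57.8-fold and without shNTC replicate 3 12.2-fold higher.

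Of 23 genes of the interferon and double-stranded RNA response, 3 rose and 12 fell (camera adjusted p = 0.169), including OAS1, which was 2.24-fold lower. Of 24 p53 targets, 15 rose and 7 fell (camera adjusted p = 0.172), and CDKN1A, which encodes the cell cycle inhibitor p21, was 3.16-fold lower, at 138.2 ± 2.06 against 437.7 ± 7.32 CPM (n = 3 each). Of 28 apoptosis regulators, 5 rose and 14 fell (camera adjusted p = 0.074, and 0.0191 without a count filter, range over the camera alternatives 0.0191 to 0.344), with PMAIP1, a pro-apoptotic gene, 5.23-fold higher and CASP10 8.25-fold lower. Of 17 Wnt targets, 6 rose and 5 fell (camera adjusted p = 0.941), with AXIN2 3.02-fold lower. Of 21 YAP/TEAD targets, 5 rose and 12 fell (camera adjusted p = 0.169), with MYOF 8.64-fold lower and AJUBA, named above, higher. Of 31 primary cilium genes, 13 rose and 5 fell (11 and 5 adjusted over the list alone, camera adjusted p = 0.214), with RPGRIP1L 2.25-fold higher. Of 12 histone genes, 5 rose and 5 fell (camera adjusted p = 0.941), with H1F0 higher and HIST2H2BE 4.10-fold lower. For the other lists not called, the counts adjusted over the list alone equalled those over all genes.

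Markers of other cell types were few. Of 7 tested fibroblast and stromal markers, 4 rose and 3 fell (camera adjusted p = 0.577), with LUM 2.37-fold higher at 45.2 ± 3.18 against 19.2 ± 0.57 CPM (n = 3 each). Of 5 endothelial markers, 1 rose and 2 fell (camera adjusted p = 0.669), and 1 of the 2 was ERG, which VCaP cells express from their fusion gene. Of the haematopoietic markers 3 genes were left after the filter, too few to test as a list, and LYZ, which encodes lysozyme, was 10.6-fold lower.

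By camera with the preset correlation, 7 of the 27 tested lists were higher and 6 lower. With an estimated correlation 0 lists passed (1 list, TGF-beta and BMP targets, had an unadjusted p under 0.05, at 0.0253), and by fry all 27 passed.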

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

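Thinning, the assumed coefficient of variation, the removal of genes in shifted runs, the list of focal adhesion genes without NEDD9 and the length and GC correction were chosen only after the results were seen. NEDD9 stayed lower under every alternative, from -1.41 to -1.37 with 1 library left out. Leaving out 1 library gave 4603 to 4937 higher and 4670 to 4997 lower genes, 1079 to 1189 at least 2-fold higher, 1328 to 1412 at least 2-fold lower, and 13 to 15 lists. Over all alternatives 7771 (assumed coefficient of variation of 10%) to 10133 (no count filter) genes were called, against 9964, and of the genes called under both, 0 had the opposite sign. The number of lists moved by more than 1.5 times only with an estimated correlation (0) and with fry (27). The 13 called lists had estimated correlations of 0.05 to 0.83, all above the preset 0.01, and fry does not compare a list with other genes. Without a count filter the lists of androgen-repressed genes, mesenchymal and basal markers and apoptosis regulators were called as well, and after thinning the first 3 of these. Of 17 alternatives tested with camera, 3, 8, 2 and 1 called them; for the mesenchymal markers these included the replicate block (camera adjusted p = 0.0456, range 2.18e-05 to 0.344). The correction for length and GC gave medians without a test, and among called lists it moved 3 by more than 1.5 times, to -0.18 (focal adhesion), -0.23 (epithelial and luminal) and -0.19 (androgen-induced). Of 2486 values for 139 named genes, 2482 kept their side of the threshold and 0 reversed; SRC passed in 3 of 18, and ENG, an endothelial marker, missed it in 1 (edgeR adjusted p = 0.295 at the assumed 10%, range 5.90e-05 to 0.295). The replicate number as a block gave 9834 calls, and the deviations of same-numbered libraries correlated by -0.05, -0.02 and 0.01, and not every library correlated best with its own number, so the numbers do not pair the libraries. DESeq2 and the assumed coefficient of variation gave no list test. Other scaling factors moved the median log2 fold change of all genes from 0.00 to at most 0.02. Depth limits small changes: the thinned libraries gave 8167 calls.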

Other observations

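The tests of replicate noise, of slowed division and of other cell types, and the 21-gene window for chromosome runs, were chosen only after the results were seen. The lists of tRNA synthetases and of gastrointestinal genes were chosen after the named genes were seen but before the values of the other members were. The criterion for other cell types was first a pooled median log2 fold change of their markers (-0.09) and was then changed to a ratio of summed CPM.

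Genes typical of gastrointestinal epithelium stood out among the decreases. Besides REG4, a look after the values were seen showed CEACAM5 13.1-fold and CEACAM6 11.8-fold lower, and the mucin gene MUC13 15.5-fold lower. A wider list that left these genes out had 16 tested members, of which 13 fell and 1 rose (median log2 fold change -1.62, camera p = 4.14e-05, and p = 0.0983 with an estimated correlation). AGR2 was 3.18-fold lower (352.4 ± 14.6 against 1117 ± 30.1 CPM, n = 3 each), TSPAN8 2.97-fold and GPX2 7.71-fold lower, whereas DPP4 was 1.58-fold higher. KRT20 had 0 counts in shNEDD9 and was at least 23.1-fold lower at a floor of 3 counts over the group, with which the median stayed at -1.62.

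Genes of cytosolic tRNA synthetases rose unequally. The 12 known as targets of ATF4, the transcription factor of the amino acid response, had a mean log2 fold change of 1.23 (SD 0.74), against 0.40 (SD 0.32) for the other 7, of which 5 rose and 0 fell. The difference of 0.84 had a two-sided exact permutation p = 0.0141 over 50388 assignments of genes, which are not independent replicates. GARS had been seen among the smallest p-values, and without it the 11 other targets had a mean of 1.15 (SD 0.72, exact permutation p = 0.0216 over 31824 assignments). Of the 12 targets 11 rose, with CARS up 4.47-fold and YARS up 3.79-fold, and IARS did not (log2 fold change -0.03). The hypothesis that ATF4 activity was higher in shNEDD9 cells is consistent with this, but ATF4 activity itself was not measured.

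The number of changed genes was weighed first. Of the 10 splits of the 6 libraries into 3 and 3, only the real one (value 1 in each of 3 counts) gave as many changed genes (9964 against at most 0), as many changed at least 2-fold (2357 against at most 0) and as many lists (13 against at most 11), but 10 splits are too few for a share under 0.05. Each other split put libraries of both shRNAs in both groups and kept part of the real contrast. The rest of it widened the spread within groups, so 0 changed genes was to be expected, which decides nothing about the gene counts. These splits still called 8 to 11 lists with 0 changed genes, so a list can be called without any changed gene. Because they kept part of the real contrast, they cannot tell how far the number of lists depends on the grouping. One library counted more than once is argued against by the lowest chi-square ratio of a replicate pair, 1.14, and a difference in depth by the 1947 genes changed at least 2-fold after thinning, 1768 of them among the 2357. Silencing of NEDD9, off-target effects of the shRNA, selection of infected cells and a shared culture of each group stay open, and may all enlarge the count. The sample numbers in the titles run on within each group, so an effect of preparation order cannot be told apart from the shRNA.

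The growth lists and the list of ER stress and amino acid response genes (the amino acid response list below) rose together. A length or GC bias is argued against by the medians of the G2/M, DNA replication and amino acid response lists, which kept at least 90.9% of their size after the correction, whereas the lower medians of the focal adhesion, epithelial and androgen-induced lists shrank to -0.18, -0.23 and -0.19. Nutrient exhaustion with slowed division in the cultures of 1 group would move the G2/M and amino acid response lists in opposite directions. All 28 G2/M genes rose (median 1.63), and of the 26 ER stress and amino acid response genes 20 rose and 4 fell (median 0.83). The G2/M genes were thus not lower in shNEDD9. Both lists being higher is the pattern itself, and the criterion was written after both were seen, so it decides nothing about exhaustion. Exhaustion stays open, with or without slowed division. Reads from stromal, blood or endothelial cells as the whole cause are argued against by markers under 1 CPM in shNEDD9 (13 of 21 stromal, 18 of 21 blood and 10 of 14 endothelial genes without ERG) and a ratio of 1.03 of the summed markers (1.12 without ENG, 41.8% of the sum in shNTC), although a small share of such cells stays open. Other scaling kept 100% of the medians but moved fold changes by almost nothing, so it decides nothing, and a higher rate of division in shNEDD9 cells may underlie these lists but was not tested apart from selection of infected cells.

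Neighbouring genes shifted together in 7 runs of the 21-gene running median (235 genes, 101 of the genes changed at least 2-fold), such as chromosome 11 from 62787415 to 64803241, where 37 of 43 genes were lower (median -0.88). The 11-gene window first used to find runs in every other gene left 11 held-out genes, of which 81.8% moved with their run (95% exact binomial interval 48.2 to 97.7), 77.8% without like-named neighbours, with an interquartile range of 2.48, too few to decide. The 21-gene window, chosen after that, gave 4 runs with 113 held-out genes, of which 77.0% moved with their run (68.1 to 84.4), against a chance order of genes. Of those without like-named neighbours 74.4% did (63.9 to 83.2), against shared reads of paralogs as the whole cause. These intervals treat neighbouring genes as independent, so they may be too narrow. Most genes of the run on chromosome 5 from 140868183 to 141651419 are protocadherins, and there shared reads stay open. Of its other genes TAF7 (log2 fold change 0.03), DIAPH1 (-0.02), HDAC3 (0.00) and RELL2 (-0.11) barely moved, and AC005618 (-1.24) and FCHSD1 (-1.19) fell. The higher run on chromosome 16 from 53391089 to 57083531 (19 of 24 genes higher) holds like-named metallothionein genes such as MT2A (1.68) and MT1E (1.72). The run on chromosome 4 from 70518540 to 82374503 holds like-named CXCL genes. Shared reads stay open for those genes too. The interquartile range of the 113 held-out genes, 0.95, was not narrower than that of all genes (0.85). A difference in DNA copy number, which could arise in selected cells, therefore cannot be told apart from shared regulation. NEDD9 itself lies outside such a shift, since its 20 nearest tested genes had a median of 0.24.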
